A study of Mus musculus with 6 samples.

How the data were processed

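The samples were 6 RNA-seq libraries of ILC2s from mouse lung, 3 treated with DMSO and 3 with 10 µM Yoda1 for 24 h. Per the labels' protocols, total RNA was isolated with a column kit for small amounts, 10 ng of RNA was used to make cDNA, and libraries followed standard Illumina protocols; per the series' design text they were sequenced on a NextSeq instrument. Groups were taken from the treatment given in the labels. The design text and the deposited table's own treatment column name the control PBS for the 3 samples that the sample labels call DMSO; the sample labels were followed. Nothing in the labels says that the libraries of a group came from separate mice or cultures, so p-values measure the spread between these libraries, which could be technical. The libraries are numbered 1 to 3 and 4 to 6, so no number pairs a DMSO with a Yoda1 library. The labels also give a library number that DMSO 2 and DMSO 3 share (19) and that Yoda1 4 and Yoda1 5 share (21). Only these libraries carry a further index after that number, which parts the libraries of a pair. Each pair could therefore be 2 libraries of 1 sample, and the groups could hold fewer than 3 independent samples. A suffix in the labels is 0 for DMSO 1 and DMSO 2 and 45 to 48 for the others. What these numbers mean is not given in the sources used here.

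The values are expected counts, that is estimated read counts per gene that need not be whole, in 1 table deposited by the authors with 17546 genes. Per the submitters' processing notes the genome build was mm10, and per the deposited table's name the Partek software was used; the aligner, the counting method, its strand setting, the annotation and the filters are not given in the sources used here. From 57.1% to 66.5% of the values of a library were whole within 0.001, and each gene had a total of at least 10 over the 6 libraries. A counting method that divides reads between near-identical genes makes single members of such families uncertain. Counts were rounded to whole numbers before any test. No gene column lacked a name.

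Total counts ran from 14214048 to 31627519 per library, and a count of 0 allows up to 0.0949 CPM in the deepest library and 0.211 CPM in the shallowest, taken as 3 counts of the total and for counting error only. Libraries of a group were compared by a chi-square test of their counts; chi-square over its degrees of freedom was at least 18.63 for every pair in a group, so no pair agreed within sampling noise, as 1 library deposited again would. This does not show that the libraries came from separate RNA or cell samples; each was counted once as the labels list it, and libraries with a shared label number were summed as an alternative. Positions came from GENCODE M21 on GRCm38, the build also called mm10; 17121 symbols matched by name and 207 through another symbol, and 17291 had a single position.

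The main test was fixed before the data were examined: edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest without covariates, and Benjamini-Hochberg adjusted p under 0.05. It kept 13325 genes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Printed CPM values are scaled by TMM and refer to the tested genes, except where they are said to be of all counts. The common biological coefficient of variation was 0.355. Groups did not overlap for 22.6% of the tested genes, where chance gives 10% for 3 against 3.

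A set of 40 gene lists, covering ILC2 function, signalling, metabolism, stress, the cell cycle, markers of other cells and RNA quality, was also fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a mean-variance trend and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry stood beside it. The text names genes by a rule from the same time. It takes the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes, pseudogenes and receptor segments. It also takes 9 genes whatever their result, and up to 4 members of each described list with the smallest p among those past the threshold, or up to 2 where none passed. Any other gene named was chosen after its values were seen. A gene that the rule selects and that is withheld is not reported here, though it stayed in the tests.

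Alternatives were other scaling factors, DESeq2 1.42.0, limma voom, no filter and a filter of 10 CPM in 3 libraries, glmTreat against a 1.5-fold change, the label suffix as a term (0 against any other number), summed libraries with a shared label number, and each library left out in turn. Added after seeing the data were DMSO 1 alone against Yoda1, voom with the label number as a random effect, and removal of each library's trends with GC content and transcript length by splines with 5 degrees of freedom, for the 13175 genes with both values. DESeq2 gave no adjusted p for 2328 genes. Where a group held 1 library, it was assumed to vary like the other group.

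The test was tested on simulated data: counts for the 13325 genes of the Yoda1 against DMSO comparison were drawn with known changes, and edgeR recovered 12.3% of 65 genes changed 1.5-fold, 25.8% of 62 changed 2-fold and 63.1% of 65 changed 4-fold, with 1 false call among 66. Small changes are therefore missed more often than not at this size. A list shifted by 0.5 on the log2 scale was called and 0 of the other lists were. The simulated genes were drawn independently and the lists at random. This does not show how the preset correlation of 0.01 performs where genes of a list move together. Estimated correlations of the real lists reached 0.873 for ribosomal proteins, and that of the mitochondrially encoded genes was 0.291. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.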

Results

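Bulk RNA-seq libraries were made from group 2 innate lymphoid cells (ILC2s), lymphocytes without antigen receptors that release type 2 cytokines such as IL-5 and IL-13. The cells were sorted from the lungs of BALB/c mice that had received 3 injections of 1 µg of IL-33, the alarmin that activates ILC2s. They were cultured with IL-2 and IL-7, at 10 ng/mL each, and exposed for 24 h to 10 µM Yoda1 or to DMSO. Yoda1 is a small molecule that opens Piezo1, a mechanosensitive calcium-permeable channel, so the comparison asks how the ILC2 transcriptome changes when this channel is activated chemically. Each group held 3 libraries, numbered DMSO 1 to 3 and Yoda1 4 to 6 as in the labels. Total counts were 18000924, 31627519 and 14214048 for DMSO 1, 2 and 3, and 15355158, 17322050 and 17104372 for Yoda1 4, 5 and 6. Levels are CPM, counts scaled to a common library total, as mean ± SD over the 3 libraries of a group (n = 3 per group). Libraries whose labels share a number may not be independent samples. Changes are log2 fold changes of Yoda1 over DMSO with their standard errors (SE).

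ILC2s exposed to Yoda1 had lower transcript levels of cell cycle genes, with 16 of 40 past the test over all genes. The cytokines Il9 and Il10 were lower, but each stayed past that test in only 2 fits with each library left out in turn. Their highest adjusted p in those fits was 0.0731 and 0.149 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Lists of cytokine signalling targets (5 of 20 members fell) and glycolysis (4 of 24 fell) were called lower by camera with a preset correlation and by fry (Benjamini-Hochberg adjusted p = 0.0402 and 0.0248), but not by camera with an estimated correlation (adjusted p = 0.37 and 0.32 with an estimated correlation). The Yoda1 libraries had higher levels of the chitinase-like protein gene Chil3, the lipid droplet coat gene Plin2, the autophagy receptor gene Sqstm1 and the inhibitory receptor gene Pdcd1. Of 13325 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 76 were higher and 123 were lower with Yoda1 at the threshold of 0.05. The gene with the smallest adjusted p was Plin2, which rose from 2104 ± 112 to 5428 ± 245 CPM, a log2 change of 1.37 (SE 0.063, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.03e-05). Plin2 lies on chromosome 4 at 86648386 to 86670060 (GRCm38).

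Among genes past the threshold that averaged at least 5 CPM and whose groups did not overlap, the largest rise was that of Chil3, from 0.775 ± 0.331 to 72.0 ± 26.0 CPM. Predicted genes, pseudogenes and receptor segments were left out. Its log2 change was 6.60 (SE 0.44, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00073). Chil3 lies on chromosome 3 at 106147554 to 106167564 (GRCm38) and encodes a secreted protein that alternatively activated macrophages also make. Pex11a, a peroxisome proliferation gene, followed at 2.27 (SE 0.43), from 1.84 ± 0.74 to 8.97 ± 1.37 CPM. Rn7sk, a short nuclear RNA that holds back transcription elongation, rose by 2.26 (SE 0.29). The adjacent heat shock genes Hspa1a and Hspa1b rose by 2.24 (SE 0.28) and 2.22 (SE 0.25), and their values are uncertain because the copies are nearly identical in sequence. Endov rose by 1.55 (SE 0.30), the biliverdin reductase gene Blvrb by 1.51 (SE 0.24), and Rgs2, a regulator of G protein signalling, by 1.48 (SE 0.26).

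The largest fall by the same rule was that of Il9, a cytokine that ILC2s release and respond to, which fell from 32.7 ± 6.9 to 2.18 ± 1.5 CPM. Its log2 change was -3.89 (SE 0.50, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0089), and the gene lies on chromosome 13 at 56479277 to 56482246. The neighbouring antiviral membrane protein genes Ifitm3, Ifitm1 and Ifitm2, within 140954837 to 141010770 on chromosome 7, changed by -3.82 (SE 0.45), -3.55 (SE 0.35) and -2.37 (SE 0.38). Their split is uncertain because the paralogs share sequence. Ly6a, which encodes the surface protein Sca-1, fell from 107 ± 3 to 17.1 ± 5.7 CPM, a log2 change of -2.64 (SE 0.25). Tnfrsf8, which encodes CD30, changed by -2.52 (SE 0.31) and Il10 by -2.11 (SE 0.36). Csf2rb, the shared receptor chain for IL-3, IL-5 and GM-CSF, changed by -2.22 (SE 0.43), with reads that could be split with its paralog Csf2rb2.

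**Figure D1:**
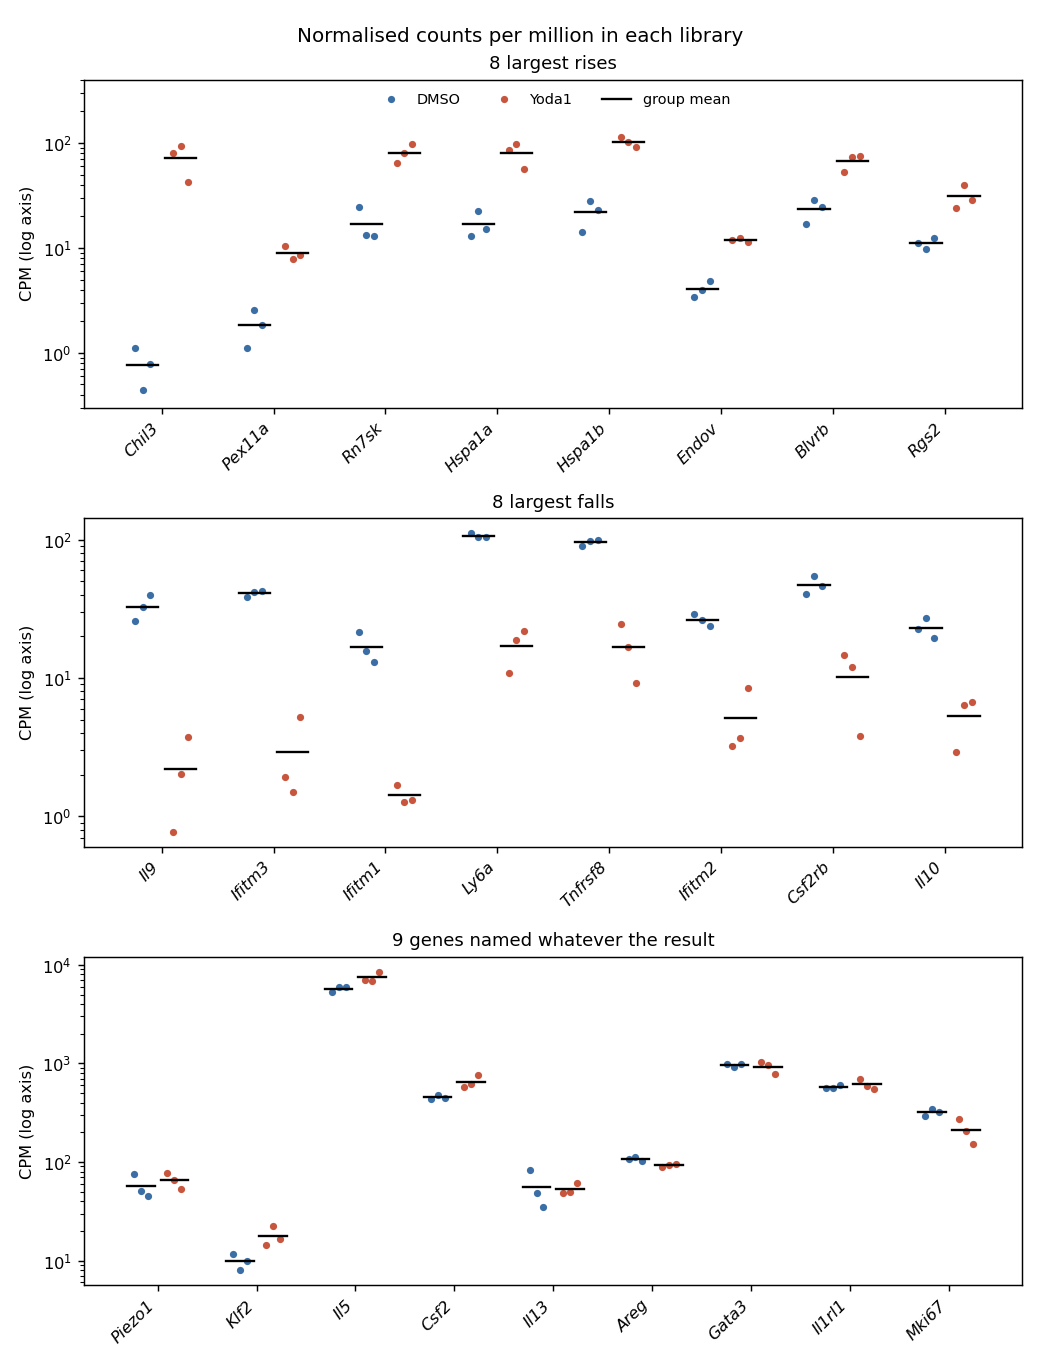
Normalised CPM of single genes on a log axis. Shown are the 8 largest rises and 8 largest falls among genes past the threshold, by the naming rule, and the 9 genes named whatever their result. Each point is 1 library (DMSO in blue, Yoda1 in red) and each black bar a group mean. In the upper panels no DMSO library overlaps a Yoda1 library, whereas in the lower panel the groups overlap for Piezo1, Il13, Gata3 and Il1rl1.

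Cell cycle genes moved lower together. All 40 tested members of the list had negative log2 changes, with a median of -0.71; 16 fell and 24 did not pass over all genes, and 34 were lower when adjusted over the list alone. Camera, a test of a list against all other genes, called the list lower (Benjamini-Hochberg adjusted p = 5.41e-31), and the call held with an estimated correlation (adjusted p = 0.0284 with an estimated correlation). Plk1, a mitotic kinase, fell from 282 ± 10 to 140 ± 11 CPM, a log2 change of -1.01 (SE 0.10). Ccnb1, which encodes cyclin B1, changed by -0.98 (SE 0.10), the ubiquitin-conjugating enzyme gene Ube2c by -1.05 (SE 0.12), and the ribonucleotide reductase gene Rrm2 by -0.79 (SE 0.08). Mki67, the proliferation marker, was at 320 ± 27 CPM with DMSO and 212 ± 60 CPM with Yoda1, and did not pass over all genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.19).

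Feedback regulators and targets of STAT5, the transcription factor downstream of IL-2 and IL-7, also moved lower as a list. Of 20 tested members 5 fell, none rose and 15 did not pass in edgeR, while DESeq2 called 8 lower and 1 higher and voom 5 and 0. Adjusted over the list alone, 8 were lower and 1 was higher; at an unadjusted p under 0.05, 10 and 1 were. The median log2 change was -0.24, and camera called the list lower (Benjamini-Hochberg adjusted p = 2.36e-05), a call that was lost when the correlation was estimated (adjusted p = 0.37 with an estimated correlation). Socs3, a suppressor of cytokine signalling, fell from 136 ± 9 to 33.8 ± 10.0 CPM, a log2 change of -2.01 (SE 0.21). The kinase gene Pim2 changed by -1.38 (SE 0.15), Lta, which encodes lymphotoxin alpha, by -1.43 (SE 0.16), and Il2ra, the alpha chain of the IL-2 receptor, by -0.67 (SE 0.08).

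The surface receptor list of ILC2s was not called (camera, Benjamini-Hochberg adjusted p = 0.71). Its members went both ways: 1 of 27 rose, 4 fell and 22 did not pass, and adjusted over the list alone 5 were higher and 6 lower. The list's median was 0.09, whereas its mean was -0.12 and the test pointed lower. Those that fell were Ly6a, Il2ra, Icos, a costimulatory receptor, from 860 ± 11 to 463 ± 35 CPM, and Tnfrsf9, which encodes 4-1BB, from 837 ± 11 to 543 ± 24 CPM. The member that rose was Arg1, the arginase that ILC2s express, from 243 ± 33 to 462 ± 15 CPM, which is an enzyme and not a receptor. Il1rl1, the IL-33 receptor, was at 576 ± 19 and 614 ± 76 CPM. Among 11 inhibitory receptors, Pdcd1, which encodes PD-1, rose from 430 ± 14 to 884 ± 51 CPM, a log2 change of 1.04 (SE 0.08); none fell in edgeR, DESeq2 or voom, or at an unadjusted p under 0.05 in edgeR, and 3 were higher when adjusted over the list alone. That list was not called (camera, Benjamini-Hochberg adjusted p = 0.36).

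Of 17 type 2 cytokines and effectors, Il9 and Il10 fell, 15 did not pass, and none rose in edgeR, while DESeq2 called 3 higher and 2 lower and voom 1 and 2; at an unadjusted p under 0.05 edgeR had 4 higher and 2 lower. Adjusted over the list alone, 4 were higher and 2 lower; the median was 0.07, the mean -0.11, and camera did not call the list (Benjamini-Hochberg adjusted p = 0.64). Il5 was at 5721 ± 358 CPM with DMSO and 7440 ± 856 CPM with Yoda1, a log2 change of 0.38 (SE 0.08, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.071). Csf2, which encodes GM-CSF, was at 453 ± 24 and 651 ± 97 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.070). Il13 was at 55.65 ± 25.07 and 53.03 ± 6.77 CPM, and the epidermal growth factor family member Areg at 107 ± 6 and 92.6 ± 2.7 CPM; neither passed. None of 20 ILC2 identity and transcription factor genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, although 3 were higher and 4 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 3 lower. Gata3, the lineage factor of ILC2s, was at 963 ± 36 and 925 ± 129 CPM, and Maf at 43.5 ± 4.3 and 21.1 ± 4.1 CPM.

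The channel that Yoda1 opens was expressed in both groups. Piezo1, on chromosome 8 at 122481698 to 122551329, was at 56.8 ± 15.9 CPM with DMSO and 65.3 ± 12.6 CPM with Yoda1, a log2 change of 0.20 (SE 0.23) that did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.75). None of 18 mechanosensitive and calcium entry channel genes passed in edgeR; 2 were higher at an unadjusted p under 0.05 and 2 were higher in DESeq2. The list was not called (camera, Benjamini-Hochberg adjusted p = 0.57). Klf2, a transcription factor that responds to fluid flow in endothelium, was at 9.88 ± 1.88 and 17.8 ± 4.1 CPM, a log2 change of 0.85 (SE 0.28, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.20). Of 16 genes in the list of KLF2 and its reported targets, none passed; adjusted over the list alone the integrin gene Itga4 was higher, at 23.9 ± 6.3 and 47.2 ± 1.4 CPM. At an unadjusted p under 0.05, 2 of these were higher and 3 lower, and DESeq2 called 1 higher and 1 lower. The median of that list was 0.16, its mean -0.02, and it was not called (camera, Benjamini-Hochberg adjusted p = 0.88). Among 31 calcium-responsive and immediate early genes, Btg2 rose by 0.58 (SE 0.11) and Irf4 changed by -1.85 (SE 0.36), while 29 did not pass; 4 were higher and 1 lower when adjusted over the list alone.

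Among metabolic lists, glycolysis was lower. Of 24 tested members 4 fell, none rose and 20 did not pass in edgeR, with 8 lower and 0 higher at an unadjusted p under 0.05, and DESeq2 called 6 lower and 0 higher, and voom 5 and 0. The list had 6 lower when adjusted over the list alone and a median of -0.22. Camera called it lower (Benjamini-Hochberg adjusted p = 3.2e-05), a call lost when the correlation was estimated (adjusted p = 0.32 with an estimated correlation). Ldha, lactate dehydrogenase A, fell from 4557 ± 70 to 3329 ± 137 CPM, and Slc16a3, a lactate exporter, from 73.4 ± 6.2 to 31.8 ± 3.7 CPM. Tpi1 changed by -0.52 (SE 0.07) and Eno1 by -0.24 (SE 0.05). Of 73 nuclear-encoded subunits of oxidative phosphorylation none passed in edgeR, where 2 were higher and 1 was lower at an unadjusted p under 0.05, nor in DESeq2 or voom; the median was 0.02. Of 25 genes of fatty acid oxidation and uptake, Plin2 rose and 24 did not pass, with 2 higher when adjusted over the list alone. Camera did not call the list (Benjamini-Hochberg adjusted p = 0.13), whereas fry called it higher (Benjamini-Hochberg adjusted p = 0.0248). The 13 mitochondrially encoded genes were called lower with a median of -0.36 (camera, Benjamini-Hochberg adjusted p = 0.027; adjusted p = 0.50 with an estimated correlation). Their changes went both ways, with 7 negative and 6 positive, and the share of all counts in genes with the mt- prefix overlapped between groups, at 0.309%, 0.296% and 0.275% in DMSO 1, 2 and 3 and 0.290%, 0.345% and 0.244% in Yoda1 4, 5 and 6. mt-Atp6 changed by -0.86 (SE 0.11) and mt-Cytb by -0.64 (SE 0.11); 11 did not pass, and adjusted over the list alone 6 were lower and 1 was higher. Camera lost the call without DMSO 1 (Benjamini-Hochberg adjusted p = 0.0954), without DMSO 2 (adjusted p = 0.0638) and without Yoda1 6 (adjusted p = 0.315).

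Lysosome and autophagy genes were called higher, with a median of 0.15 (camera, Benjamini-Hochberg adjusted p = 0.0085; adjusted p = 0.25 with an estimated correlation). Of 30 tested members 2 rose, none fell and 28 did not pass in edgeR, while DESeq2 called 5 higher and 1 lower and voom 2 and 0. Adjusted over the list alone, 4 were higher and 1 lower; at an unadjusted p under 0.05, 7 and 1 were. Sqstm1, which encodes the cargo receptor p62, rose from 780 ± 31 to 1841 ± 33 CPM, a log2 change of 1.24 (SE 0.07), and Gabarapl1 rose by 0.98 (SE 0.18). The list of NRF2 targets, which respond to oxidative stress, was called higher with a median of 0.23 (camera, Benjamini-Hochberg adjusted p = 0.015; adjusted p = 0.34 with an estimated correlation). The quinone reductase gene Nqo1 rose by 0.42 (SE 0.07) and 20 of 21 members did not pass; adjusted over the list alone 5 were higher and 1 lower, and the call was lost without DMSO 1 (adjusted p = 0.0536). Of 23 genes of the unfolded protein response and heat shock, Hspa1a and Hspa1b rose and the disulfide isomerase gene Pdia6 changed by -0.68 (SE 0.08), with 2 higher and 7 lower when adjusted over the list alone. That list was not called (camera, Benjamini-Hochberg adjusted p = 0.060), and its median of -0.16 and a test that pointed lower differed in sign from its mean of 0.06. In the NF-kB list Tnfaip3 and Relb rose, by 1.40 (SE 0.27) and 0.74 (SE 0.13), while Lta, Bcl3 and Nfkb1 fell; Bcl3 changed by -1.32 (SE 0.16) and Nfkb1 by -0.74 (SE 0.09). The other 16 of its 21 members did not pass, 6 were higher and 4 lower when adjusted over the list alone, and camera did not call it (Benjamini-Hochberg adjusted p = 0.26).

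**Figure D2:**
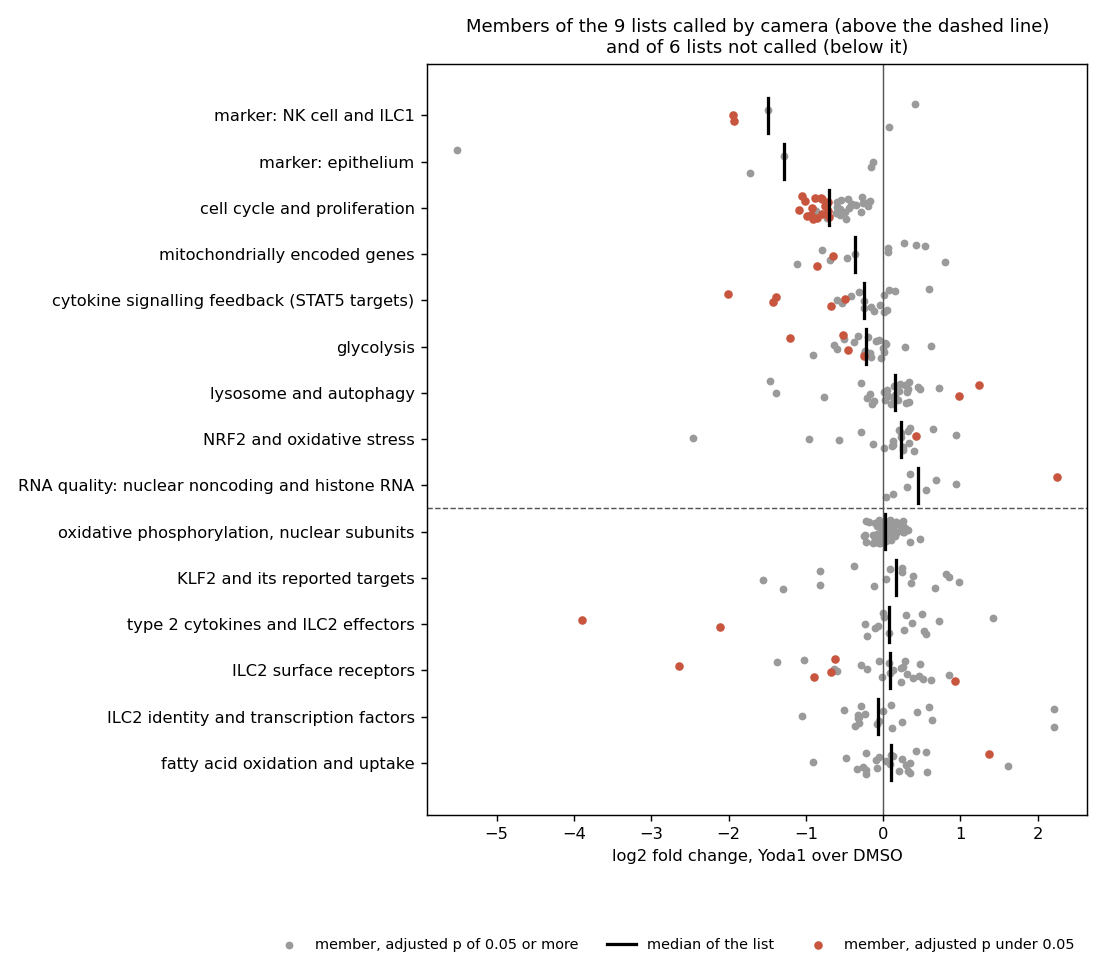
Log2 fold change of Yoda1 over DMSO for every tested member of the 9 lists that camera called (above the dashed line) and of 6 lists that it did not call (below it); red points passed the test over all genes, grey points did not, and black bars are list medians. All 40 cell cycle genes lie below 0, while the 73 nuclear-encoded oxidative phosphorylation genes lie around a median of 0.02.

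Markers of other cells and of RNA quality moved as well. The epithelial list was called lower (camera, Benjamini-Hochberg adjusted p = 0.028; adjusted p = 0.37 with an estimated correlation), although none of its 5 tested members passed in edgeR over all genes, 1 was lower at an unadjusted p under 0.05 and 1 was lower when adjusted over the list alone. That member, the surfactant protein gene Sftpa1, was at 3.75, 21.3 and 21.7 CPM in DMSO 1, 2 and 3 and at 0, 0.923 and 0.0597 CPM in Yoda1 4, 5 and 6. Scgb1a1, the club cell secretory protein gene, was detected in too few libraries for the test: it was at 301.7 and 293.3 CPM of all counts in DMSO 2 and DMSO 3, at 0.0585 CPM in Yoda1 6, and at 0 in DMSO 1, Yoda1 4 and Yoda1 5. A count of 0 there allows up to 0.167, 0.195 and 0.173 CPM, as far as counting error goes. Without DMSO 2 the epithelial call by camera was lost (adjusted p = 0.0901), and likewise without DMSO 3 (adjusted p = 0.0609). It held without DMSO 1 (camera, adjusted p = 7.99e-09), where the median was -5.975 against -1.285. It also held without Yoda1 4, 5 or 6, with medians of -4.961, -7.923 and -5.02. Genes were filtered anew in each fit, so the tested members could differ. The list of natural killer cell and ILC1 markers was called lower (camera, Benjamini-Hochberg adjusted p = 0.027; adjusted p = 0.38 with an estimated correlation), through the granzyme genes Gzmb and Gzma, which changed by -1.94 (SE 0.19) and -1.93 (SE 0.25). The other 3 tested members did not pass, both granzymes were lower when adjusted over the list alone, and the call was lost without DMSO 2 (adjusted p = 0.0926) and without Yoda1 4 (adjusted p = 0.214). The RNA quality list held nuclear and other noncoding RNAs and also Lars2, a protein-coding gene. It was called higher (camera, Benjamini-Hochberg adjusted p = 0.00037, and 0.23 with an estimated correlation). All 8 tested members had positive changes, with a median of 0.45. Rn7sk rose, 7 did not pass, and 3 were higher when adjusted over the list alone. Fry also called this list higher (Benjamini-Hochberg adjusted p = 0.018). The call by camera held whichever library was left out (Benjamini-Hochberg adjusted p of at most 0.0029). Whether RNA quality differed between the groups was not tested by another measure. Of 6 tested macrophage and monocyte markers Chil3 rose and 5 did not pass; 2 were higher when adjusted over the list alone, and the list was not called by camera (Benjamini-Hochberg adjusted p = 0.096) but was called higher by fry (Benjamini-Hochberg adjusted p = 0.0231).

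Of 40 lists, 35 had the 5 tested members needed. Camera with a preset correlation called 9, and the 26 not called had adjusted p from 0.0597 to 0.883. With an estimated correlation camera called 1. The lost calls cannot all be put down to the correlation. The RNA quality and lysosome lists had estimated correlations of -0.0261 and -0.0185, below the preset 0.01. Their unadjusted camera p still went from 4.19e-05 to 0.0133 and from 0.00122 to 0.0213. Fry, which tests whether the genes of a list move one way on balance and not against other genes, called 7 lists, of which 5 were among the 9. It did not call the mitochondrially encoded (Benjamini-Hochberg adjusted p = 0.105), NRF2 (0.0912), natural killer cell (0.0761) and epithelial (0.116) lists. With the label suffix as a term, camera with Benjamini-Hochberg adjustment lost the calls of the mitochondrially encoded (adjusted p = 0.322), NRF2 (0.110), lysosome and autophagy (0.0595), natural killer cell (0.0901) and epithelial (0.0662) lists. In that fit the natural killer cell median went from -1.486 to -0.0007. The other medians were -0.2761 for mitochondrially encoded, 0.2245 for NRF2, 0.1371 for lysosome and autophagy and -1.41 for epithelial genes. The granzymes did not follow the natural killer cell median. Over all alternatives Gzma stayed between -2.107 and -1.502 and Gzmb between -2.153 and -1.727. That list had 5 tested members, among them Nkg7, at 0.778, 1.99 and 0 CPM of all counts in DMSO 1, 2 and 3. With DMSO 1 alone against Yoda1 the natural killer cell and epithelial medians were -0.7123 and -0.5232, against -1.486 and -1.285 in the main fit. Camera lost the epithelial call with summed libraries (Benjamini-Hochberg adjusted p = 0.0783). It lost the mitochondrially encoded call with the trends in GC content and transcript length removed (0.0743), where the median was -0.306 against -0.3648. Other single members that passed in lists not called were Slc3a2, Bnip3, Vim and Tpm4, which fell, and Cxcr6, a chemokine receptor gene, which rose from 2357 ± 49 to 3221 ± 295 CPM. Vim, the intermediate filament gene, fell from 1649 ± 49 to 981 ± 62 CPM.

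The counts of single genes changed with the library left out: 9 genes were higher and 25 lower without DMSO 1, 9 and 13 without DMSO 2, 4 and 5 without DMSO 3, 7 and 27 without Yoda1 5, 47 and 100 without Yoda1 4, and 74 and 146 without Yoda1 6. Yoda1 6 stood apart from its group, at -72.8 on the second principal component (24.1% of the variance) against 45.21 and 33.0 for Yoda1 4 and Yoda1 5. Chi-square over its degrees of freedom was 51.56 and 36.92 between it and those libraries, against 25.08 between Yoda1 4 and Yoda1 5. As Yoda1 4 and Yoda1 5 share a label number, a common origin of theirs and an outlying Yoda1 6 cannot be told apart. DMSO 2 and DMSO 3, which also share one, were at 21.13. DMSO 1 was at 26.02 with DMSO 2 and at 18.63 with DMSO 3. This ratio grows with depth, and DMSO 1, 2 and 3 had totals of 18000924, 31627519 and 14214048 counts. The order of these values therefore does not show which DMSO pair was closest. Summing the libraries whose labels share a number left 1 higher, Plin2, and 0 lower in edgeR (703 higher and 809 lower at an unadjusted p under 0.05), and a term for the label suffix, coded as 0 for DMSO 1 and DMSO 2 against any other number for DMSO 3 and the Yoda1 libraries, left Plin2 and Sqstm1 higher and Aqp9 lower. With upper-quartile scaling 57 genes were higher and 174 lower, and with trends in GC content and transcript length removed 201 were higher and 177 lower. With DMSO 1 alone, without the libraries that held Scgb1a1, the median log2 change was -0.6366 for the cell cycle list and -0.5232 for the epithelial list. This fit rests on 1 DMSO library. DMSO 1 was not free of epithelial transcripts: Sftpc, a surfactant protein gene, was at 15.33 CPM of all counts there, against 0.569 and 0 in DMSO 2 and DMSO 3. Chil3, Plin2, Sqstm1, Pdcd1, Ly6a and Ifitm1 were the 6 of 50 named genes past the threshold that stayed past it whichever single library was left out. Il9 and Il10 stayed past it in 2 of the 6 such fits each, and Pex11a and Endov in 0.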

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

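All alternatives named here were planned except the 3 added after seeing the data: DMSO 1 alone, the random effect and the removal of trends. No paired analysis was possible because the groups share no replicate numbers. Counts are of genes higher and lower with Yoda1, against 76 and 123. They were 401 and 459 with DESeq2, with 72 and 117 shared, 121 and 179 with voom, 151 and 213 with voom and the label number as a random effect, and 201 and 177 with the GC and length trends removed. They were 158 and 290 with the stricter filter, which tested fewer genes, and 50 and 83 with no filter, which tested more. Against a 1.5-fold change they were 6 and 10. With the label suffix as a term they were 2 and 1, with summed libraries 1 and 0, and with DMSO 1 alone 0 and 0, each from a comparison resting on fewer samples. Leaving out 1 library gave 4 to 74 higher and 5 to 146 lower. For the differences between tools and for the trends, the cause was not tested. Lists called numbered 9, with 1 with an estimated correlation, 7 with fry (5 shared), 4 with the label suffix as a term, and 6 to 12 with 1 library left out. All 50 named genes past the threshold kept their sign in all alternatives, and none of them stayed past it in all; of 47 not past it, 24 kept sign and side and 6 changed sign. Log2 changes of the other sign, none past the threshold, came with the label suffix as a term for Il13 (0.5868), Cd79b (0.2272) and Pdgfrb (7.042), which is near the floor. Il13 was also at 0.005909 with voom, 0.01633 with the random effect and 0.03828 with the trends removed. Piezo1 was at -0.000913 with summed libraries and -0.2045 with DMSO 1 alone. Leaving out 1 library turned the sign of Il13 (0.3463) and Pdgfrb (1.368) without DMSO 1, Cd79b (0.05208) without DMSO 2, Il1rl1 (-0.01484) without Yoda1 4 and Gata3 (0.05048) without Yoda1 6; the cause was not tested. Over the 6 such fits the ranges were -0.3187 to 0.3463 for Il13, -3.726 to 1.368 for Pdgfrb, -0.345 to 0.05208 for Cd79b, -0.01484 to 0.1563 for Il1rl1 and -0.1438 to 0.05048 for Gata3. Depth limits the genes near the floor, which is 0.0949 to 0.211 CPM per library.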

Other observations

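Beyond the lists, several genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; they were chosen after their values were seen, and no theme was tested for them. Among those that fell, the channel gene Aqp9 went from 89.1 ± 8.0 to 20.9 ± 1.2 CPM, the amino acid transporter gene Slc7a8 from 768 ± 71 to 277 ± 59 CPM, and the motor protein gene Myo6 from 1857 ± 40 to 924 ± 50 CPM. Cyp11a1, the first enzyme of steroid hormone synthesis, fell from 2992 ± 111 to 1969 ± 137 CPM, the leukotriene receptor gene Cysltr1 from 358 ± 17 to 244 ± 21 CPM, and the receptor gene Il10ra from 126 ± 5 to 68.1 ± 14.7 CPM. Among those that rose, the MHC class I genes H2-K1, H2-D1 and H2-T23 had log2 changes of 0.30 (SE 0.06), 0.28 (SE 0.05) and 0.61 (SE 0.10). H2-K1 and H2-D1 are close paralogs, so their split is uncertain. The lipid droplet gene Hilpda rose from 119 ± 3 to 236 ± 31 CPM, and the uridine phosphorylase gene Upp1 from 62.9 ± 3.5 to 163 ± 30 CPM.

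Of the tests that follow, those of macrophage RNA, of a shared preparation and of carried-over reads were chosen only after the result was seen. So was the use of the label suffix to test the cell cycle pattern, although that fit was planned. The removal of GC and length trends was added after the data were seen, and the PPAR list after the rises of Plin2 and Pex11a were. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 199 genes and the highest other split 0, with 1 of 10 as large; the real split gave 9 lists and the highest other 7, again with 1 of 10 as large.

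The lower cell cycle list could come from the library batch that the label suffix may mark, or from GC content and length. With the suffix as a term the median was -0.709, and with the GC and length trends removed it was -0.681, against -0.71, and camera still called the list lower in both, which argues against either as the whole cause. The suffix term rests on DMSO 3 alone to part the batch from the treatment. Slower division of Yoda1-treated cells is a hypothesis that fits these values and was not tested by another measure.

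The rise of Chil3 could come from macrophages or monocytes left in the sort, whose gate is not given in the labels. The predicted rise of the other 12 measured markers of these cells was not met. Their median rise was 0.0275 CPM of all counts against 71.19 CPM for Chil3, and the largest, that of Lyz2, was 6.435 CPM. These values cannot decide the source, because several markers stayed near the floor, such as Csf1r at 0.219 CPM with DMSO and 0.143 CPM with Yoda1. How much Chil3 such cells hold beside these markers was also not measured. Ccr2 did not rise, at 189 CPM with DMSO and 173.8 CPM with Yoda1. It was so far above the other markers that most of it need not come from macrophages or monocytes. Fry called the marker list higher (Benjamini-Hochberg adjusted p = 0.0231). Chil3 itself is among the 6 tested members and the list was not tested without it, so this call is no separate evidence. RNA from macrophages or monocytes is not excluded. Whether ILC2s themselves express Chil3 after Yoda1 stays open, since no test here assigns reads to cells.

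Scgb1a1, Retnla, Chia1, Cbr2, Krt8, Inhba, Krt19 and Nebl, chosen after their values were seen, were at 5 CPM or more in DMSO 2 and DMSO 3 and under 10% of that in DMSO 1. Nebl was also at 10.55, 4.214 and 7.367 CPM in Yoda1 4, 5 and 6. Carry-over from the other 4 libraries of the series is argued against by Scgb1a1, which reached at most 0.0585 CPM there. This does not cover carry-over between DMSO 2 and DMSO 3 or from libraries outside the series. A shared cell preparation behind the libraries with a common label number stays open: 8 genes had this pattern, against 3 and 1 for the other DMSO pairs, and 10 against 6 and 2 for Yoda1 4 and 5 and the other Yoda1 pairs. The prediction asked only for more genes, which was met, but counts this small do not separate 10 from 6, and voom's correlation within a shared number was -0.0618. The prediction did not weigh levels. In DMSO 2 and DMSO 3 Scgb1a1 was at 301.7 and 293.3 CPM of all counts and Retnla at 101.5 and 104.5 CPM. Chia1 was less close, at 34.72 and 21.74 CPM. Levels as close as those of Scgb1a1 and Retnla would go with a shared preparation, but were not tested. Epithelial cells left in the sort of DMSO 2 and DMSO 3 are a candidate source of these transcripts. Epithelial transcripts were not confined to these libraries. Sftpc, a surfactant protein gene on the epithelial list, was at 15.33 CPM in DMSO 1, 0.569 CPM in DMSO 2 and 0 in DMSO 3. Epcam, on the same list, was at 67.83, 64.63 and 65.5 CPM in DMSO 1, 2 and 3. In Yoda1 4, 5 and 6 it was at 58.35, 48.78 and 70.1 CPM. It did not follow Scgb1a1, so it does not bear on the epithelial content of DMSO 1.

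Plin2 and Pex11a, both PPAR targets, led to the hypothesis of a general rise of PPAR target genes, tested on a list without them that was written after these rises were seen. Camera called the 33 tested genes higher, with a median log2 change of 0.263 (SD 0.626, 25 of 33 positive, Benjamini-Hochberg adjusted p = 0.0242). With an estimated correlation the unadjusted p was 0.131, no member rose in edgeR, Ucp2 fell from 1472 ± 71 to 1039 ± 117 CPM, and 13 of the 33 were also in the fatty acid list, which camera did not call (Benjamini-Hochberg adjusted p = 0.13) and fry called higher (Benjamini-Hochberg adjusted p = 0.0248). As camera called up to 7 lists in other splits of these libraries, the hypothesis remains weak.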
